A study of Homo sapiens with 2 samples.

How the data were processed

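The series holds 2 libraries from TL-Om1, an established human cell line of adult T-cell leukaemia. In the ChIP library, chromatin was immunoprecipitated with an antibody against TP73, a transcription factor of the p53 family. The input library is whole cell extract taken as background. Per the labels' protocols, cells grown in RPMI-1640 with 10% serum received 10 min of formaldehyde cross-linking, and single-end reads of 50 bases were produced on the DNBseq platform. Each group has 1 library, so nothing measures the spread between cultures, and every p-value below describes positions within this peak list, not TL-Om1 cultures.

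The values used are the authors' peak list, which holds 18908 peaks of the ChIP library. Per the submitters' processing notes, Bowtie2, SAMtools and MACS2 were used with the hg19 build; the parameters, the order of steps and the treatment of duplicate reads are not given in the sources used here. For each peak the deposited file gives a position, a fold enrichment (a ratio of the ChIP pileup to the local background at the summit), the −log10 of the peak's p-value and of its q-value, a score, and the distance of the summit from the start. These are the authors' values for each peak. The deposited score equals the whole part of 10 times the −log10 p-value for 18903 peaks and differs from it for 5. The labels name whole cell extract as the control, whereas the names of all 18908 peaks contain the text IgG; which control library the caller was given is therefore not settled here, and "control" below means that library. Positions are on hg19 and counted from 1.

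Read totals are not part of the peak list. They were approached through the caller's own arithmetic. MACS2 gives the fold as (pileup + 1) / (background + 1) and the p-value as a Poisson tail of the whole part of the pileup, so each pair of values was solved for pileup and background. All 18908 peaks had a solution, and 112 had more than 1. For these, solutions whose background fitted the genome-wide level or one of the windows described below came first. Among them, the solution nearest to a whole number of reads was kept. The background match of these 112 peaks is therefore partly built in. A first attempt took the pileup as a whole number of unscaled reads and failed (the solved pileup is whole at 2.43% of peaks), and a scaling of the ChIP reads was then allowed. On peaks at the lowest common background, 1 ChIP read was worth 0.975 units of pileup. The other 8976 peaks with a single solution were not used to fit that step, and 100% of them gave a whole number of ChIP reads within 0.01 reads, where 2% would pass by chance. The background was 2.41 control reads per 142 bp, or 16.9 per kb, at 9820 peaks. This genome-wide level was the lowest background used, so fewer control reads near these peaks would not show. At the other 9088 peaks the background equalled a whole number of control reads in a window of 142 bp, 1 kb or 10 kb around the summit, within 0.02 reads. After each background had been shifted at random, 16.8% matched. The length of 142 bp is that of the shortest peaks and of the caller's fragment. If the caller's usual human effective genome size of 2700000000 bp was used, the background corresponds to about 45800000 control reads and 46900000 ChIP reads after the caller's filters; this size is an assumption, and the totals depend on it. On 2000 simulated peaks with known reads and backgrounds, the method recovered the ChIP reads of 100% and the window behind the background of 96.3%, and 1.65% of peaks passed as whole after fold and p-value had been shuffled apart. The simulated values were made with the same formulas that the method solves. The simulation therefore checks the solving, not whether those formulas hold for the deposited peaks.

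Peaks per Mb were computed over the span from the first to the last summit of each chromosome, with exact 95% Poisson intervals. This replaces the planned non-gap length, because a sequence of the hg19 build was not used here. Intervals cover counting error only. Autosomes were compared with 100000 random draws of the peaks in proportion to span. Medians were compared between chromosomes with 10000 two-sided permutations of peaks, Benjamini-Hochberg adjusted over 6 tests, and neighbouring peaks are not independent. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

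The comparisons, the alternatives and the rule for named regions were fixed before the data were examined, except the recovered reads, the background by chromosome, the medians of reads and of fold on chromosomes 15 and X, the spacing of peaks, and the alternatives named in the closing section as added, which were chosen afterwards. Without an annotation of hg19, the rule names the 15 peaks with the highest −log10 q-value by position. The planned descriptions of promoters, of p53-family and other motifs, and of 16 fixed gene lists need the sequence or annotation of hg19 and were not analysed here; the gene table at hand is of another assembly (GRCh38) and was not used to place peaks.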

Results

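TP73 occupancy was profiled by ChIP-seq in TL-Om1 cells, with 1 ChIP library and 1 input library. The question was where in the genome TP73 antibody enriched DNA over background. The peak list was called on the single ChIP library, so no value below has a replicate error. The depth behind the peaks was recovered from the fold and p-value of each peak.

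TP73 antibody enriched 18908 regions that together covered 5.58 Mb of hg19. The peaks were narrow, with a median width of 255 bp and quartiles of 195 and 349 bp. The shortest width, 142 bp, was shared by 416 peaks, and the widest peak spanned 1716 bp. The median fold enrichment over the control was 11.3, with quartiles of 8.31 and 18.7. Fold enrichment was at least 10 at 11304 peaks (59.8%), at least 20 at 4340 peaks (22.95%) and at least 50 at 669 peaks (3.54%). The −log10 q-value had a median of 30.4 and a minimum of 6.55. It reached 100 at 3116 peaks (16.5%). Wider peaks had higher folds (Spearman's rho = 0.73 across peaks, which are not independent replicates). Width and fold both come from the caller's pileup, so this relation is not a separate result about TP73 binding. The summit lay near the middle of the peak, at a median of 49.4% of its width.

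The 15 regions with the highest −log10 q-values had folds from 78.2 to 81.6 and lay on 9 chromosomes. The first was on chromosome 19 at 48021235 to 48021908, with a fold of 81.6 and a −log10 q-value of 445.9. Another region of chromosome 19, at 47734312 to 47734929, had a fold of 79.9, tied in fold and q-value with regions on chromosomes 1 and 20. Chromosome 11 held the second region, at 65188391 to 65189170 with a fold of 78.8, and the ninth, at 64889475 to 64890028 with a fold of 79.3. Chromosome 1 held 3 of the regions, at 44047766 to 44048396 (fold 80.8), 12206331 to 12206944 (fold 79.9) and 43406508 to 43407258 (fold 78.7). The region on chromosome 4 lay at 175255618 to 175256314 and had a fold of 80.2. Chromosome 20 held regions at 49461003 to 49461659 (fold 79.9) and 33999651 to 34000179 (fold 79.0). Chromosome 5 held regions at 150994749 to 150995446 (fold 79.6) and 53966933 to 53967556 (fold 78.7). The remaining regions were on chromosome 14 at 23005666 to 23006423 (fold 78.5), chromosome 9 at 94909447 to 94910027 (fold 78.5) and chromosome 10 at 104401824 to 104402962 (fold 78.2). The region on chromosome 10 was the widest of the 15, at 1139 bp. At 14 of the 15 regions the fold was taken over the genome-wide background, so no local window of the control exceeded that level. Between 272 and 284 ChIP reads covered these summits, so their order rests on differences of few reads. The first and second region both had 284 reads and differed only in the control background, 2.41 against 2.53 reads. No peak had more than 284 reads, and 5 peaks reached that number. Only the first and second region of the 15 are among these 5, since equal reads over a higher control background rank lower. If 284 reads is a ceiling, a candidate taken up in the closing section, the order of these regions does not measure strength of enrichment.

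Over all peaks, a median of 43 ChIP reads covered the summit, with quartiles of 31 and 73 and a minimum of 18. At 9820 peaks (51.9%) the background used was the genome-wide level of 2.41 control reads per 142 bp. That level is a floor, so the control reads at these summits may be fewer. At 1580 peaks (8.36%) at least 142 ChIP reads covered the summit. The highest value was 284 reads, reached by 5 peaks.

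**Figure D1:**
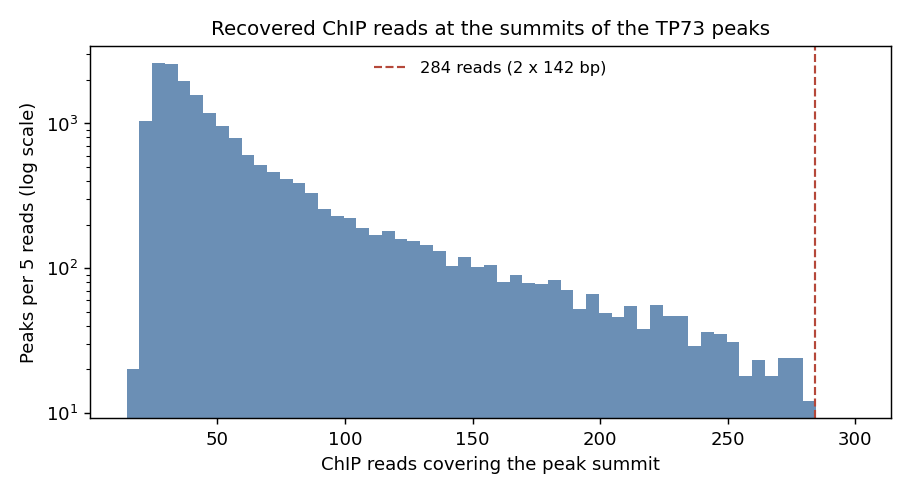
Number of peaks (log scale) by the number of ChIP reads covering the summit, in steps of 5 reads, for all 18908 TP73 peaks. The counts fall from a median of 43 reads to the highest value of 284 reads (dashed line), which is 2 times the fragment length of 142 bp.

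TP73 peaks were spread unevenly over the chromosomes. The gene-rich chromosomes 22, 19 and 17 carried the densest sets, with 11.97 peaks per Mb (95% Poisson interval 10.8 to 13.2), 11.8 (10.9 to 12.7) and 11.2 (10.5 to 11.96). With the longest peak-free interval of each chromosome left out of its span, chromosome 19 came first with 13.1 peaks per Mb and chromosome 22 second with 12.6. Chromosome 15 followed these 3 with 9.71 peaks per Mb (9.05 to 10.4). The sparsest autosomes were chromosome 4, with 4.33 peaks per Mb (4.04 to 4.64), chromosome 6, with 4.59 (4.28 to 4.93), and chromosome 18, with 4.74 (4.27 to 5.25). Chromosome X carried 331 peaks, or 2.14 per Mb (1.91 to 2.38), against 6.65 per Mb over the 22 autosomes together. Chromosome 22 was 2.76 times as dense as chromosome 4 (95% interval 2.45 to 3.11). The pair was picked as the densest and sparsest of the 22 autosomes, and the interval does not allow for that pick. The spread over autosomes exceeded counting error (p = 1e-05, one-sided permutation test that placed peaks at random in proportion to span, the smallest that 100000 draws can give). Intervals and random draws treat peaks as independent, although summits lie closer together than random positions. These densities are not corrected for assembly gaps, gene content or copy number.

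**Figure D2:**
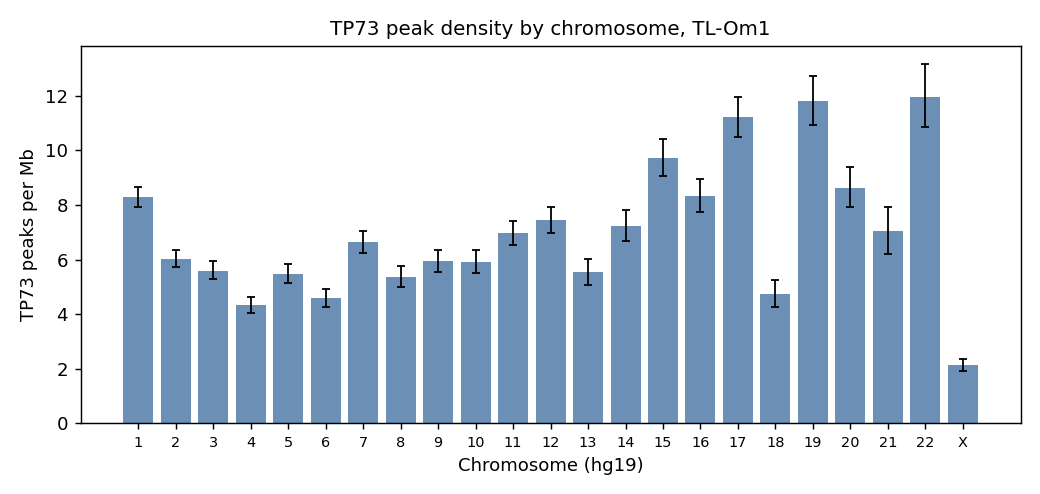
TP73 peaks per Mb between the first and last summit of each autosome and chromosome X. Bars are the density in the 1 ChIP library and error bars the exact 95% Poisson interval; chromosomes 22, 19 and 17 exceed 11 peaks per Mb and chromosome X has 2.14.

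The control background behind the folds also differed between chromosomes. On chromosome X, 90.03% of peaks were scored against the genome-wide background, and on chromosome 19 the share was 72.5%. On chromosome 15 it was 0.754%, because local control reads exceeded that level at almost every peak. Chromosome 1 beyond 200 Mb had a share of 0.368% over 544 peaks, against 46.5% over its other 1518 peaks. Chromosome 7 beyond 80 Mb had a share of 2.19% over 594 peaks, against 72.3% over its other 459 peaks. On chromosome 12 the share was 0% between 30 and 40 Mb, 2.96% between 120 and 130 Mb and 71.0% beyond 130 Mb. High shares were not confined to chromosome X. Chromosome Y had a share of 85.7%. On chromosome 6 the bins of 10 Mb had shares of 89.5% to 97.4% from 0 to 60 Mb and of 86.3% to 100% from 80 to 120 Mb. The share on chromosome 6 was 34.8% between 70 and 80 Mb, 63.2% between 120 and 130 Mb and 41.7% to 46.4% in the bins from 130 to 170 Mb. The difference between chromosomes, over the autosomes and X, exceeded that of 10000 shuffles of the peaks (p = 0.0001, permutation test, the smallest these can give). Peaks were shuffled singly, although neighbouring peaks can share control windows and are not independent.

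**Figure D3:**
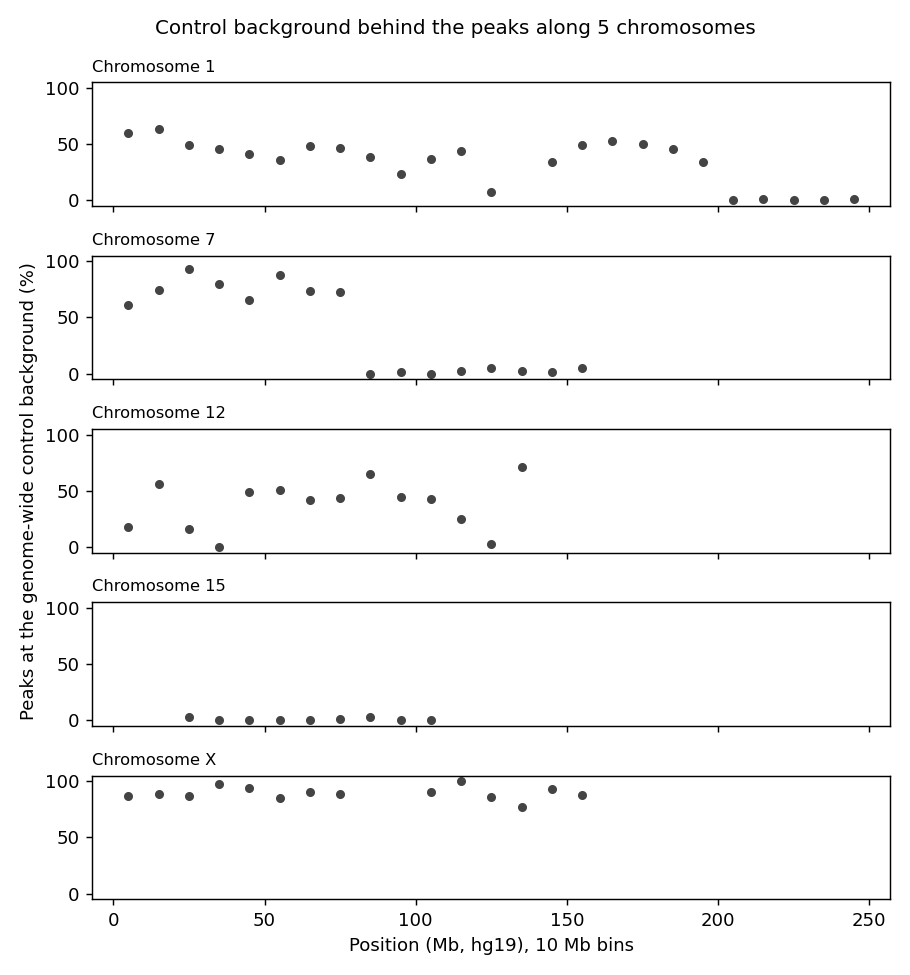
Share of peaks (%) scored against the genome-wide control background in bins of 10 Mb with at least 10 peaks, along chromosomes 1, 7, 12, 15 and X. Each point is 1 bin; the share is near 0 over chromosome 15, chromosome 1 beyond 200 Mb and chromosome 7 beyond 80 Mb, and high along chromosome X.

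Chromosome 15 ranked differently by fold and by reads. Its peaks had a median of 49 ChIP reads at the summit against 43 on the other autosomes (permutation test, adjusted p = 0.0003). A higher background raises the reads a peak needs to be called, and among peaks with at least 30 reads, a limit added after seeing the data, the medians were 52 and 51 (permutation test, adjusted p = 0.73). That limit cuts on the reads compared and can hide a shift that brings weaker peaks over it. The source of the difference between 49 and 43 is therefore not settled. The median fold on chromosome 15 was 10.6 against 11.4 over all peaks and 11.3 against 13.3 among peaks with at least 30 reads; the fold is divided by the background, which was raised there, so this difference is not a separate result. On chromosome X the median was 41 reads against 43 on the autosomes (permutation test, adjusted p = 0.49), and the median fold was 11.7 against 11.3 (permutation test, adjusted p = 0.42). Some sites of high control coverage had folds below the median of 11.3 over all peaks. The 1 peak on the mitochondrial sequence, at 252 to 397, had the lowest fold of the list, 1.62, with 217 ChIP reads over 130 control reads. A peak on chromosome 1 at 236260381 to 236260653 had a fold of 3.32, with 118 ChIP reads over 34 control reads. On chromosome 9, a peak at 68413758 to 68414312 had a fold of 8.41 with 275 ChIP reads, since 31 control reads covered the same summit.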

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

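The difference in median ChIP reads between chromosome 15 and the other autosomes, 6 reads over all peaks, was 1 read among peaks with at least 30, a limit added after seeing the data. The number of peaks and the contrast of chromosomes 22 and 4 changed little under the planned limits. A −log10 q-value of at least 5 removed no peak, so it tests nothing. A limit of 10 left 18523 peaks, a fold of at least 5 left 18783, and merging peaks closer than 500 bp left 17842. The ratio of the densities of chromosomes 22 and 4 stayed between 2.70 and 2.84, against 2.76 as deposited, over these limits and over those added after seeing the data (at least 50 ChIP reads, no mitochondrial peak, span less its longest gap and, for this ratio, merging). Requiring at least 50 ChIP reads at the summit left 7915 peaks, so the number of peaks depends on that limit. Under it, chromosome 15 rose to 1.71 times the autosomal density from 1.46. No density of chromosomes 15, 17, 19 or X moved to the other side of the autosomal density under any setting run. The alternatives for promoters, motifs and gene lists, and the filter on repeat-rich and pericentromeric peaks, were not run, since each needs hg19 sequence or annotation. With 1 library per group, no library could be left out. No paired analysis was possible because the list comes from 1 ChIP library and 1 control. At the lower end the weakest peaks rest on 18 ChIP reads and a −log10 p-value of at least 9.27; sites below the limit of calling were not analysed here.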

Other observations

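TP73 summits were spread over most of the genome, and a few windows were unusually dense. The densest windows of 1 Mb were chromosome 11 from 65 to 66 Mb and chromosome 9 from 139 to 140 Mb, with 48 peaks each, followed by chromosome 19 from 1 to 2 Mb with 47 and chromosome 11 from 64 to 65 Mb with 45. The median over the 2603 windows with a peak was 5, and the highest count in 200 shuffles within chromosomes was 28. At a scale of 100 kb, chromosome 1 from 25200001 to 25300000 held 18 peaks with a highest fold of 42.2. Chromosome 8 from 145000001 to 145100000 held 17. Chromosome 10 from 104400001 to 104500000 held 14, among them the region ranked 15th by q-value. Peaks near each other were not much alike in strength, with 3 distance classes tested. Spearman's rho of their ChIP reads was 0.05 for 1318 neighbours up to 1 kb apart (adjusted p = 0.078, permutation test). For 3266 neighbours 1 to 10 kb apart it was 0.01 (adjusted p = 0.55, permutation test), and for 7825 neighbours 10 to 100 kb apart 0.03 (adjusted p = 0.042, permutation test).

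All tests below were chosen after the results were seen, as were the limits that define the raised stretches (at least 3 bins of 10 Mb in a row, each with under 10% of peaks at the genome-wide background). They bear on hypotheses found in this same peak list.

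Close spacing was the first pattern. Neighbouring summits up to 1 kb apart numbered 1318, against a mean of 140.9 in shuffles within chromosomes (permutation p = 0.001, the smallest that 1000 shuffles can give). Uneven density over megabases did not account for all of it, since the pairs were still 5.87 times as many as in shuffles inside windows of 1 Mb. Splitting of single enriched regions by the caller stays open. Pairs 1 to 10 kb apart were 1.19 times as many as in shuffles inside windows of 100 kb (3266 against a highest shuffled count of 2869), which splitting of longer regions and other clustering would both give. In 23.1% of the pairs up to 1 kb less than a fragment length lay between the peaks. A neighbour within 1 kb was found for 17.4% of peaks in the lowest quartile of ChIP reads and 10.7% in the highest. Whether splitting gives that difference was not tested, and no biological explanation was tested.

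The second pattern was the raised control background over chromosome 15, chromosome 1 beyond 200 Mb and chromosome 7 beyond 80 Mb. For the differences between 23 whole chromosomes, chance among single peaks is argued against, with a chi-square of 2436 against at most 62.3 in shuffles. These shuffles treated neighbouring peaks as independent, although neighbours can share control windows. They did not test the stretches themselves. The raised level was not confined to a few peaks of the stretches, but whether repeats collapsed in the reference lie near them was not tested. With the stretches defined on every other peak, 0.564% of 532 other peaks inside them, each over 10 kb from any peak used, stood at the genome-wide background (95% exact binomial interval 0.116 to 1.64), against 56.1% of 5050 such peaks elsewhere. Both sets come from the same list, where the share over all peaks of the stretches was already 1.09%. The low value was therefore nearly fixed in advance and is no separate support. Its interval treats neighbouring peaks as independent. More copies of these stretches in the cells may be the reason, which remains open, and the answer depends on which peaks are counted. The median control background was 1.39 times that at other autosomal peaks, whose median is the genome-wide level. That level is the lowest background used and holds at 57.0% of those peaks. The value of 1.39 is thus not a ratio of control coverage. Over all peaks, the first comparison made, the median of ChIP reads was 1.09 times that of other autosomal peaks (95% bootstrap interval 1.07 to 1.14), the upper quartile 1.10 times and the 90th percentile 1.06 times (0.985 to 1.16). A higher background also raises the fewest reads a peak needs (21 in the stretches, 18 elsewhere), so the comparison was then repeated on peaks with at least 30 reads, where the geometric mean was 1.01 times (0.982 to 1.04) and the median 0.98 times (0.942 to 1.02). That limit can in turn hide a shift that brings weaker peaks over it. Peaks were denser in all 3 stretches: 11.1 per Mb against 7.60 in the rest of chromosome 1, 7.54 against 5.76 in the rest of chromosome 7, and 9.71 on chromosome 15 against 6.56 on the other autosomes, with gene content not accounted for. Chromosome 15 was 1.46 times as dense as the autosomes together over all peaks and 1.71 times among peaks with at least 50 ChIP reads. The cause of that rise was not tested, and the other stretches were not compared at this limit. Over 23 whole chromosomes, which dilute the stretches, no relation of control level and density passed the test (Pearson's r = 0.26, permutation p = 0.23; Spearman's rho = 0.19, permutation p = 0.38; r = -0.08 without chromosomes X and 15).

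The third pattern was the end of the range at 284 ChIP reads. That number is 2 times the fragment length of 142 bp, which is the most that a summit can carry if at most 1 read is kept per position and strand. With 5 peaks at 284 and 0 above, this is a candidate explanation, and it would make the folds of the strongest regions lower limits. A natural, gradual end of the range is argued against: peaks fell from 207 at 227 to 255 reads to 116 at 256 to 284 and 0 at 285 to 313, whereas the steepest fall between such intervals from 140 reads up would have left 65.0 in the last. That steepest fall, to 0.56 of the interval before, was the one just below 284, and an exponential fall fitted below 255 reads gave 162.4 peaks where 116 were seen, so the range was already thinning before it stopped. No biological explanation was tested.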
